A study of Homo sapiens with 9 samples.

How the data were processed

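Strand-specific, rRNA-depleted total RNA libraries were made from 1 µg of RNA per sample, per the labels' protocols, from HEK293T cells transfected with an empty pIRES vector, TET1-ALT or TET1-FL by lipofection and harvested 4 days later. There were 3 groups of 3 samples, which the series' design text calls biological triplicates, and groups and replicate numbers were taken from the sample titles. The submitters' processing notes name TopHat2, HTSeq and Cuffdiff and the build hg19, with no version, role or order. Gene filter, scaling method and annotation are not given in the sources used here.

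The deposited table has 1 row per gene symbol and 1 column per sample. Its name says FPKM, but the values are a signal of scaled fragment counts that the authors did not divide by gene length: in each deposited column the smallest value that recurs in at least 20 genes was a step shared by genes of any length. Of the values under 300 steps, 86.2% to 89.4% per library lay within 0.03 steps of a whole multiple, so the rest are estimates or carry shared fragments, and no count model was used. The tests had been planned for FPKM before the data were examined; the unit differs, and the planned limma test on log2 values was kept. A pseudocount of 10, a mean of at least 50 and voom were therefore added as alternatives. The column total divided by the step gave the implied depth (M, mega), from 6.84 M fragments in TET1-FL replicate 1 to 37.0 M in TET1-ALT replicate 1. A value of 0 allows up to 3 fragments, which is a value of 1.55 in TET1-ALT replicate 1 and 8.22 in TET1-FL replicate 1, covering counting error only. A listed 0 can also be a failed estimate: 307 genes had a 0 in some library, and 13 of them had at least 100 in another. The table holds 22 names that a spreadsheet had turned into dates, 2 of them duplicated, and these were tested but not named. Values of paralogs and of overlapping or read-through genes are uncertain, since shared reads could be split between them. No genomic coordinates are given, since the annotation at hand is of another build.

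Values were taken as deposited. Genes with a mean of at least 0.5 over all 9 samples were tested (13895 of 13979) on log2(value + 0.5) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend), with all 9 samples in a model of group means and two-sided moderated tests. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The contrasts were TET1-FL minus empty vector, TET1-ALT minus empty vector and TET1-FL minus TET1-ALT, plus an F test over the 3 groups. Fold changes understate the change of genes with low values. On simulated data for the TET1-FL against empty vector comparison, with 13876 genes in the test and 50 genes changed at each size, 36% of 1.3-fold, 68% of 1.5-fold, 98% of 2-fold and 100% of 4-fold changes were recovered, with 6 false calls among 157. The changed genes were drawn from those with a mean of at least 50. Counts were drawn independently for each gene, and no library was made to stand apart. The rates therefore need not hold for weaker genes or for the real libraries.

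Fixed gene lists, 34 in number, were written before the data were examined, and the 31 with at least 5 measured members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists. The lists of mitochondrially encoded mRNAs, clustered protocadherins and metallothioneins had too few measured members. The lists not called in any comparison were DNA methylation machinery, p53 targets, apoptosis regulators, NF-kB and inflammatory genes, unfolded protein response, hypoxia targets, glycolysis, G2/M genes, imprinted genes, HOX genes, WNT targets, epithelial, neuronal, kidney, leukocyte and erythroid genes, and abundant long noncoding RNAs. Named genes were chosen by a rule set beforehand. TET1 came first. Then came the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap and whose higher mean was at least 1, leaving out small RNA, LOC, LINC and clone-based names. The rule added the 4 members with the smallest p in each called list, TET2, TET3, DNMT1, DNMT3A, DNMT3B and UHRF1, and the 5 genes with the smallest p where fewer than 5 passed. Some genes that the rule names are not reported here. With 3 against 3 libraries, 10% of genes have groups that do not overlap by chance.

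Alternatives set beforehand were other pseudocounts and filters, 3 scalings (median of ratios, quantile, equal totals), the replicate number as a block, only the groups compared, no variance trend, array weights, an estimated correlation for lists, and leaving out each library in turn. Added after seeing the data were, besides those above, the removal of a trend on transcript length and GC content (values for 96.8% of tested genes, from GENCODE release 29 on GRCh38, used only for these properties), the omission of empty vector replicate 1 and TET1-FL replicate 1 together, and the shared-effect values without TET1 and SLCO5A1. Replicate libraries of a group differed by more than sampling noise, with chi-square per degree of freedom from 5.24 to 45.6 over genes with a mean of at least 100, so each was counted as a sample. Those of empty vector replicate 1 with its own group were 40.1 and 45.6, against 7.19 for replicates 2 and 3.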

Results

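RNA was sequenced from 9 cultures of HEK293T, a readily transfected human embryonic kidney cell line that carries the SV40 large T antigen. The cells had received an empty pIRES plasmid, a plasmid for full-length TET1 (TET1-FL) or a plasmid for TET1-ALT, a shorter isoform. TET1 is a dioxygenase that oxidizes 5-methylcytosine in DNA. Each group had 3 biological replicates, and RNA was taken 4 days after transfection. The deposited table lists 13979 genes with a scaled fragment value for each library, and 13895 of them were tested. Column totals lay between 18.7 and 19.99 M. The depth implied by the smallest recurring value in each column was 28.4, 30.6 and 19.9 M fragments for empty vector replicates 1, 2 and 3. It was 37.0, 28.1 and 12.5 M for TET1-ALT replicates 1, 2 and 3, and 6.84, 16.9 and 12.4 M for TET1-FL replicates 1, 2 and 3. Empty vector replicate 1 stood apart on the first principal component, which held 28.5% of the variance, with a score of -22.8 against -3.53 to 12.6 in the other 8 libraries. TET1-FL replicates 1, 2 and 3 lay at the opposite end, at 5.29, 11.9 and 12.6, and the TET1-ALT libraries between, at -0.97 to 0.85. All fold changes are on the log2(value + 0.5) scale, errors after a log2 fold change are SE, and adjusted p-values come from limma with Benjamini-Hochberg adjustment unless camera is named.

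TET1 itself was examined first, as a check of which libraries came from cells that overexpressed it. A value per gene cannot tell the TET1-FL from the TET1-ALT plasmid. TET1 averaged 1730 ± 536 (SD, n = 3) in the empty vector libraries, 29457 ± 2456 in TET1-ALT and 31550 ± 1802 in TET1-FL. It was 17.6-fold higher in TET1-ALT than in the empty vector (log2 4.14, 95% interval 3.75 to 4.52, adjusted p = 1.19e-07) and 18.9-fold higher in TET1-FL (log2 4.24, interval 3.85 to 4.62, adjusted p = 5.97e-08). All 6 overexpressing libraries lay above all 3 empty vector libraries. TET1 did not differ detectably between the isoforms (log2 0.10, interval -0.28 to 0.48, adjusted p = 0.813). These values add endogenous and plasmid transcripts of TET1, and a longer transcript yields more fragments per molecule, so similar values do not give the ratio of molecules.

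**Figure D1:**
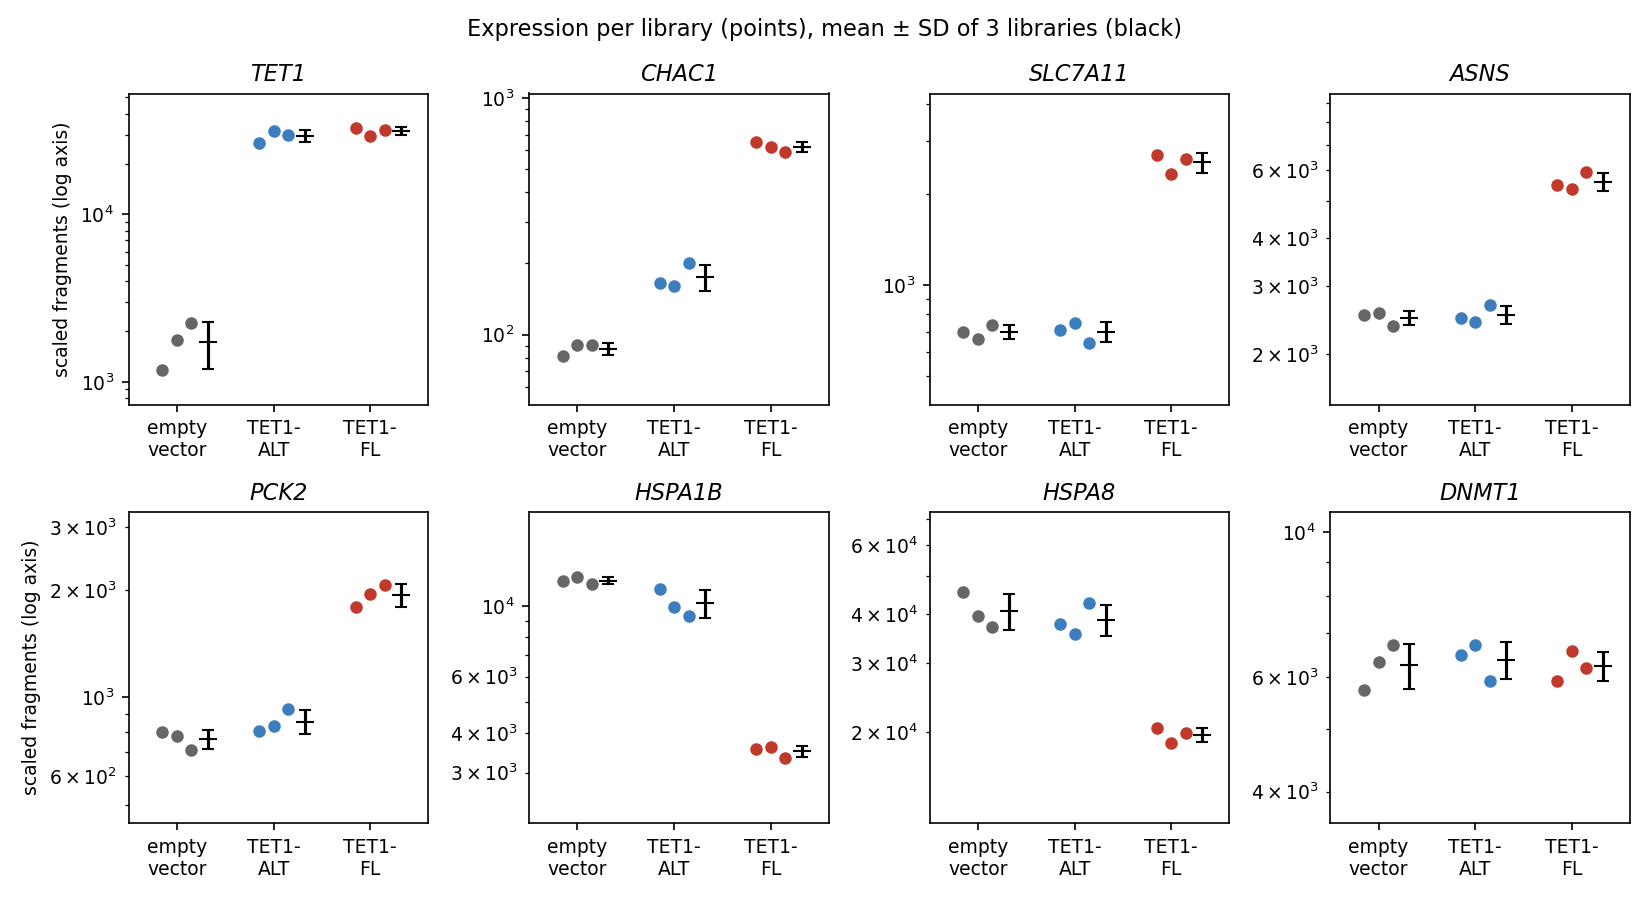
Scaled fragments (log axis) of 8 genes in each library (points: gray, empty vector; blue, TET1-ALT; red, TET1-FL), with the mean ± SD of 3 libraries in black. TET1 was at a similar level in both overexpressing groups, whereas SLC7A11 averaged 698 in the empty vector, 699 in TET1-ALT and 2555 in TET1-FL, and HSPA1B averaged 12006, 10192 and 3499.

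Expression of full-length TET1 was compared with the empty vector to find which transcripts change. In the list of the amino acid response driven by the transcription factor ATF4, 19 of 29 genes rose, and 6 of 22 heat shock protein genes fell. Camera placed the former list higher and the latter lower, and the call for the heat shock proteins was lost with an estimated correlation (adjusted p = 0.433 with an estimated correlation). CHAC1, which encodes a glutathione-degrading enzyme, rose from 87.1 ± 5.30 to 622 ± 30.3 (SD, n = 3; log2 2.83 ± 0.11, adjusted p = 5.12e-08). SLC7A11, the cystine-glutamate antiporter subunit, rose from 698 ± 38.4 to 2555 ± 190 (log2 1.87 ± 0.08, adjusted p = 9.70e-08), and ASNS, asparagine synthetase, rose from 2484 ± 107 to 5604 ± 302 (log2 1.17 ± 0.07, adjusted p = 2.47e-06). HSPA1B, a stress-inducible Hsp70, fell by 1.78 on the log2 scale, from 12006 ± 321 to 3499 ± 146 (adjusted p = 9.70e-08). HSPA8, the constitutive Hsc70, fell by 1.05, from 40705 ± 4290 to 19641 ± 859 (adjusted p = 0.000210).

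Among the other genes with the largest rises were FUT1, a fucosyltransferase (log2 1.89), PCK2, mitochondrial phosphoenolpyruvate carboxykinase (1.35), DDIT4, an inhibitor of mTORC1 (1.33), the AP-1 family repressor JDP2 (2.46-fold) and SLC6A9, a glycine transporter (1.18), with adjusted p-values from 3.27e-06 to 0.00141. ADM2 (1.27, adjusted p = 0.0180) and CLUL1 (1.36, adjusted p = 0.0419) were weakly expressed. So was FUT1, at 26.7 in the empty vector and 104 in TET1-FL. SLCO5A1 was listed at 0 in all 3 empty vector libraries and at 238 to 285 in TET1-FL, so no fold is given. Among the largest falls, DNAJB1 (-0.71, adjusted p = 0.00110) and DNAJA1 (-0.69, adjusted p = 0.0121) encode co-chaperones of Hsp70, and CD3EAP (-0.78, adjusted p = 0.00841) encodes an RNA polymerase I subunit. LUC7L2 (-0.82, adjusted p = 0.0118) encodes a splicing factor, and UTP3 (-0.67, adjusted p = 0.0458) a ribosome assembly factor. GALNT8 (-1.16, adjusted p = 0.0449) and HSH2D (-1.03, adjusted p = 0.0435) had low values, and passed under 11 and 12 of 24 alternatives. SRGAP2B (-4.40), HSPA1A (-1.64) and the read-through gene TEN1-CDK3 (-1.58), also listed among the largest falls, share sequence or exons with a partner, and their values are uncertain. HSPA1A and HSPA1B are near-identical, and their sum fell from 12067 ± 323 to 3521 ± 139 (SD, n = 3).

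In total 274 genes passed an adjusted p of 0.05, 134 higher and 140 lower in TET1-FL, of which 24 changed by at least 1 on the log2 scale. With each library rescaled to the same total, 212 were higher and 131 lower. The count depended on the libraries: it was 776 without empty vector replicate 1, 59 without empty vector replicate 2, 123 and 121 without TET1-ALT replicates 1 and 2, and 77, 84 and 57 without TET1-FL replicates 1, 2 and 3. It was 54 when only the 6 libraries of both groups were fitted, and 1201 after a trend on transcript length and GC content, which differed between libraries, was removed.

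Of the 29 measured members of the fixed ATF4 amino acid response list, 19 rose, none fell and 10 did not pass. Adjusted over the list alone, 27 rose and 1 fell. The list median was 0.52, and the list was higher by camera (adjusted p = 1.09e-34), also with an estimated correlation between genes (adjusted p = 0.00111 with an estimated correlation). Of the 22 heat shock proteins, 6 fell and 16 did not pass, and adjusted over the list alone 10 fell and 1 rose. Their median was -0.21, and camera placed the list lower (adjusted p = 5.79e-07), a call lost with an estimated correlation (adjusted p = 0.433 with an estimated correlation). Relative to the empty vector mean the median of this list was 0.15 in empty vector replicate 1, which stood apart, against -0.05 and -0.10 in replicates 2 and 3. The median was -0.12 without empty vector replicate 1 and TET1-FL replicate 1 together. The 5 genes HSPA1B, HSPA1A, HSPA8, DNAJB1 and DNAJA1 were followed by HSPH1 (-0.36, adjusted p = 0.0419), chosen after its value was seen, which passed under 15 of 25 alternatives.

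Camera called 9 further lists, and each of these calls was lost with an estimated correlation. In the cholesterol biosynthesis list (24 measured, median -0.14, adjusted p = 0.000418, and adjusted p = 0.433 with an estimated correlation) NSDHL fell (-0.37, adjusted p = 0.0449), while HMGCS1 (-0.37) had an adjusted p-value of 0.0565. Adjusted over the list alone, 7 fell, and the list median was -0.08 without empty vector replicate 1. In the list of extracellular matrix and mesenchymal genes (27 measured, median 0.13, adjusted p = 0.000816, and adjusted p = 0.433 with an estimated correlation) the collagen genes COL3A1 (0.66, adjusted p = 0.0293) and COL6A2 (0.32, adjusted p = 0.0419) rose and 25 did not pass. Adjusted over the list alone, 2 rose. SPARC (0.25) and COL6A1 (0.22) had adjusted p-values of 0.117 and 0.125. In the TGF-beta and BMP target list (18 measured, median 0.15, adjusted p = 0.00562, and adjusted p = 0.329 with an estimated correlation) ID4, an inhibitor of basic helix-loop-helix factors, rose (0.42, adjusted p = 0.0241), and ID2 (0.30), SMAD6 (0.34) and NOG (0.42) had adjusted p-values of 0.0689 to 0.110. Adjusted over the list alone, 4 rose, and the list call ended without empty vector replicate 1 and TET1-FL replicate 1 together (median 0.10, adjusted p = 0.0665).

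In the G1/S and replication list (40 measured, median -0.05, adjusted p = 0.0140, and adjusted p = 0.714 with an estimated correlation) the flap endonuclease gene FEN1 (-0.41, adjusted p = 0.0388) and the origin licensing gene CDC6 (-0.32, adjusted p = 0.0429) fell, whereas CCNE1 (-0.27) and E2F8 (-0.45) had adjusted p-values of 0.0689 and 0.0740. Adjusted over the list alone, 5 fell. The list call ended without empty vector replicate 1 (adjusted p = 0.231), and the median was -0.09 without empty vector replicate 3, and -0.03 and -0.08 without TET1-FL replicates 1 and 3. Among 120 zinc finger genes of chromosome 19 (median -0.09, adjusted p = 0.00562, and adjusted p = 0.714 with an estimated correlation) ZNF776 (-0.43, adjusted p = 0.0208) and ZNF480 (-0.37, adjusted p = 0.0449) fell. ZNF776 passed under 19 of 25 alternatives and ZNF480 under 10. Adjusted over the list alone, 3 fell, and the list call ended without TET1-FL replicate 2 (median -0.04, adjusted p = 0.297). Among 55 replication-dependent histone genes (median 0.20, adjusted p = 3.47e-05, and adjusted p = 0.714 with an estimated correlation) HIST1H2BF rose (0.39, adjusted p = 0.0378), also adjusted over the list alone, and 54 did not pass. Relative to the empty vector mean the histone median was 0.24, 0.27 and 0.04 in TET1-FL replicates 1, 2 and 3, and 0.17 in empty vector replicate 1. In the ribosomal protein list (73 measured, median 0.07, adjusted p = 0.0163, and adjusted p = 0.823 with an estimated correlation) no member passed over all genes or adjusted over the list alone. RPL10 had a log2 fold change of 0.20 and RPL13A of 0.20. The ribosomal median was 0.16 without empty vector replicate 1 and 0.12 without TET1-FL replicate 3, and the call ended without empty vector replicates 2 (0.03) and 3 (0.02) and TET1-FL replicates 1 (0.04) and 2 (0.07). The absence of members that passed also held for the 28 interferon-stimulated genes (median 0.10, adjusted p = 0.0211, and adjusted p = 0.329 with an estimated correlation), among which DTX3L was at 0.36 and STAT2 at 0.30. That call ended without empty vector replicate 3 (median 0.14, adjusted p = 0.101), without TET1-FL replicate 2 (0.07, adjusted p = 0.05004) and with quantile normalization (0.03). The median was 0.16 with array weights, 0.17 with voom and 0.17 without empty vector replicate 1 and TET1-FL replicate 1 together, with the call kept. No member passed either among the 29 TET1 partners and Polycomb or SIN3A complex members (median -0.10, adjusted p = 0.0340, and adjusted p = 0.433 with an estimated correlation), among which EED was at -0.31, SUZ12 at -0.23 and CBX2 at -0.21, and the call ended without empty vector replicate 3 (adjusted p = 0.217) and TET1-FL replicate 3 (median -0.06, adjusted p = 0.140).

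None of the 29 genes of the DNA methylation machinery list passed in TET1-FL over all genes, and adjusted over the list alone 1 rose and 1 fell. The log2 fold changes were -0.12 ± 0.10 for TET2, -0.17 ± 0.15 for TET3, -0.02 ± 0.10 for DNMT3A, 0.05 ± 0.06 for DNMT3B and -0.15 ± 0.10 for UHRF1, with adjusted p-values from 0.428 to 0.920. DNMT1, the maintenance methyltransferase, averaged 6253 ± 499 in the empty vector and 6230 ± 325 in TET1-FL (SD, n = 3), and the 95% interval of its log2 difference was -0.18 to 0.17.

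**Figure D2:**
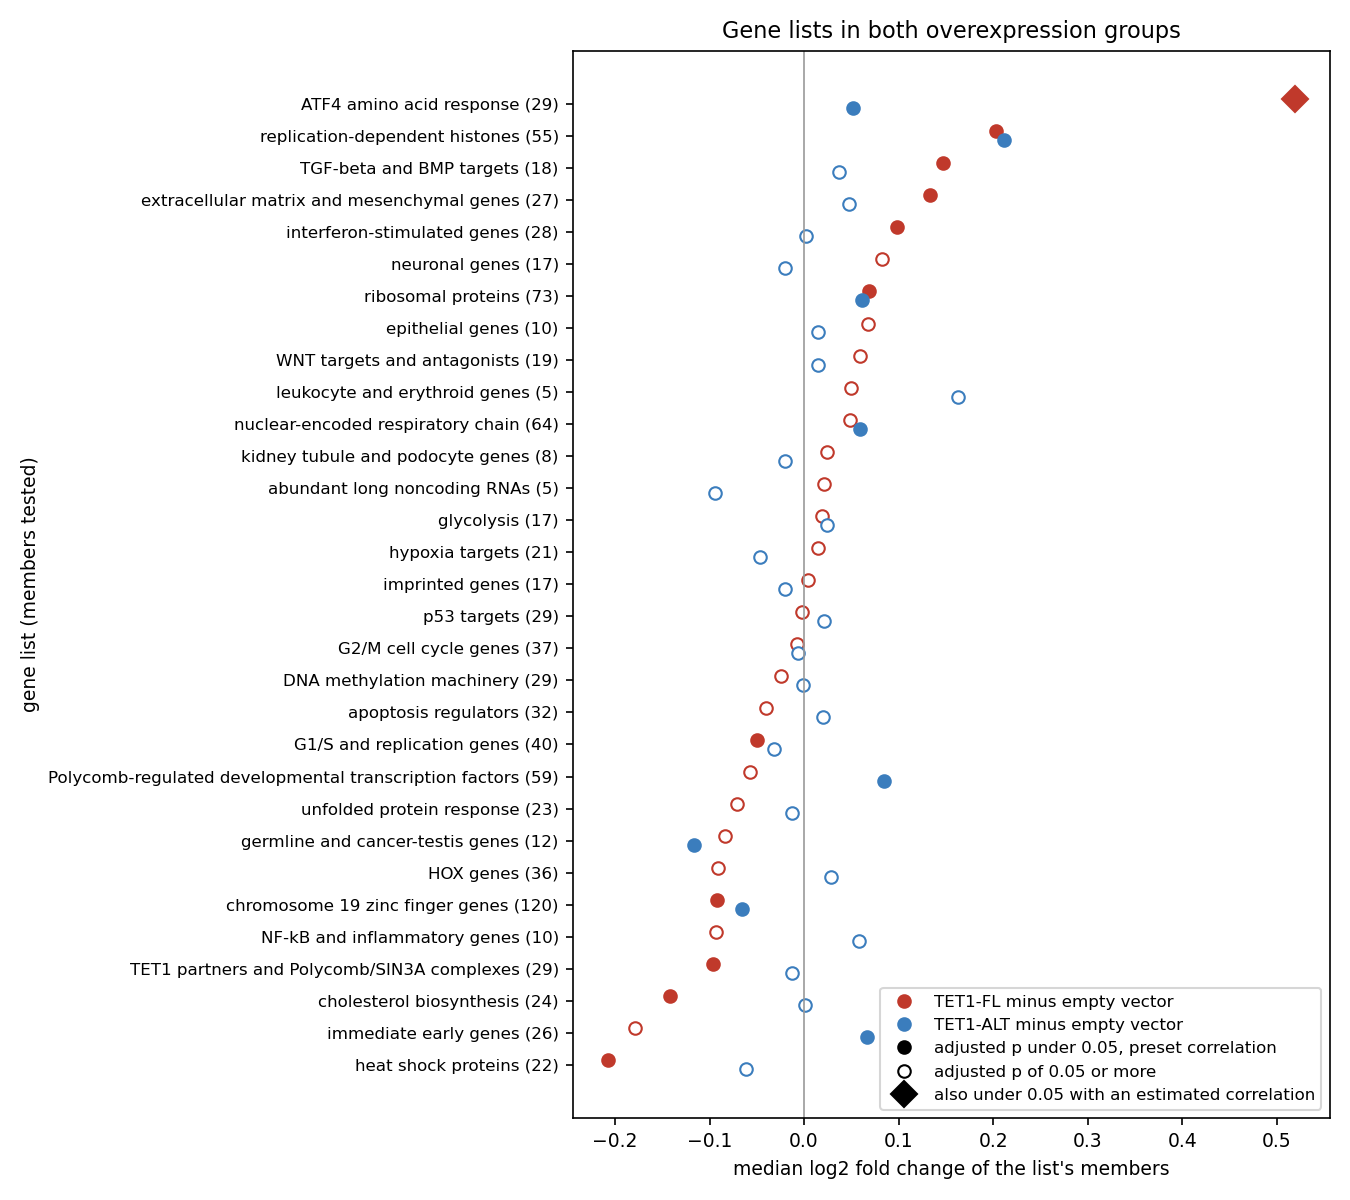
Median log2 fold change (x axis) of the members of each of 31 gene lists (y axis, members tested in brackets) in TET1-FL (red) and TET1-ALT (blue), both minus the empty vector. Filled symbols had a camera adjusted p under 0.05 with the preset correlation, and the diamond also with an estimated one. The ATF4 list in TET1-FL, at 0.52, was the highest point and the sole diamond.

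Expression of TET1-ALT was compared with the same empty vector libraries. Apart from TET1, CHAC1 rose from 87.1 ± 5.30 to 175 ± 21.8 (SD, n = 3; log2 1.00 ± 0.11, adjusted p = 0.00531), with all 3 TET1-ALT libraries above all 3 empty vector libraries. SLC7A11 averaged 699 ± 53.8 in TET1-ALT against 698 ± 38.4 (log2 difference 0.00, 95% interval -0.18 to 0.18), and ASNS averaged 2523 ± 137 against 2484 ± 107 (interval -0.13 to 0.18). SLCO5A1 was listed at 251 to 264 in TET1-ALT and at 0 in the empty vector libraries. The read-through gene C1orf151-NBL1 fell (-0.72, adjusted p = 0.0475) while NBL1, which shares its exons, went from 6.68 to 378 (adjusted p = 0.0563, not passing). The sum of both was 798 ± 41.2 in the empty vector and 859 ± 65.5 in TET1-ALT, so the values of NBL1 and C1orf151-NBL1 taken separately are uncertain.

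These 4 genes, TET1, SLCO5A1, CHAC1 and C1orf151-NBL1, were all that passed by limma in TET1-ALT, 3 higher and 1 lower. With each library rescaled to the same total 4 were higher and 0 lower. At an unadjusted p of 0.05, 265 genes passed, against 695 expected by chance. Without empty vector replicate 1 the unadjusted count was 859 and 5 genes passed the adjusted threshold. The CHAC1 call was lost when only the 6 libraries of both groups were fitted (adjusted p = 0.0804, range over 25 alternatives 0.00381 to 0.0804), and C1orf151-NBL1 passed under 14 of 25 alternatives (adjusted p from 0.00661 to 0.397).

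Camera called 8 lists in TET1-ALT, and none of these calls held with an estimated correlation. In the ATF4 list (29 measured, median 0.05, adjusted p = 9.84e-06, and adjusted p = 0.158 with an estimated correlation) CHAC1 rose and 28 members did not pass, and adjusted over the list alone 3 rose. The median was 0.09 without empty vector replicate 2, and 0.08 and 0.09 without TET1-ALT replicates 1 and 2. CEBPB was at 0.46 ± 0.10, DDIT4 at 0.32 ± 0.08 and SESN2 at 0.27 ± 0.09. No member of the other called lists passed over all genes or adjusted over the list alone. The 55 histone genes had a median of 0.21 (adjusted p = 2.73e-20, and adjusted p = 0.515 with an estimated correlation), with 52 members above 0, among them HIST1H3D at 0.47 and HIST3H2A at 0.40. The median over the histone genes, relative to the empty vector mean, was 0.11 in TET1-ALT replicates 1 and 2 and 0.45 in replicate 3, and 0.17 in empty vector replicate 1. The histone median was 0.11 without TET1-ALT replicate 3. The ribosomal protein list (73 measured, median 0.06, adjusted p = 0.00118, and adjusted p = 0.891 with an estimated correlation) and the nuclear-encoded respiratory chain list (64 measured, median 0.06, adjusted p = 0.000230, and adjusted p = 0.891 with an estimated correlation) turned to medians of -0.016 and -0.016 without TET1-ALT replicate 3. Their medians were 0.148 and 0.144 without empty vector replicate 1, and both calls ended without empty vector replicate 2 (0.024 and 0.016) and replicate 3 (0.0085 and 0.00097). Without TET1-ALT replicate 2 they were 0.112 and 0.095, and the ribosomal median was 0.098 without TET1-ALT replicate 1. The developmental transcription factor list (59 measured, median 0.08, adjusted p = 0.00155, and adjusted p = 0.515 with an estimated correlation) held NKX6-1 at 0.39 and IRX3 at 0.27. Its median turned to -0.0092 without empty vector replicate 1 (adjusted p = 0.602), and its call also ended without TET1-ALT replicate 1 (median 0.03). The immediate early list (26 measured, median 0.07, adjusted p = 0.00771, and adjusted p = 0.515 with an estimated correlation) held IER2 at 0.29 and JUND at 0.27, and its call ended without empty vector replicate 1 (adjusted p = 0.243). The zinc finger list of chromosome 19 (120 measured, median -0.07, adjusted p = 8.13e-05, and adjusted p = 0.515 with an estimated correlation) held ZNF814 at -0.36 and ZNF256 at -0.34, and its call ended with the length and GC trend removed (median -0.0097). The germline list (12 measured, median -0.12, adjusted p = 0.0231, and adjusted p = 0.425 with an estimated correlation) held SYCP3 at -0.97 ± 0.54 and MAGEC2 at -0.33 ± 0.20. This call ended without empty vector replicates 1, 2 and 3 (adjusted p = 0.0547, 0.0550 and 0.228) and TET1-ALT replicates 1 and 2 (adjusted p = 0.0562 and 0.0568). TET2 (-0.05), TET3 (-0.01), DNMT1 (0.03), DNMT3A (-0.00), DNMT3B (0.04) and UHRF1 (0.03) had adjusted p-values of 1.00 in TET1-ALT.

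The isoforms were also compared directly, which tests whether they differ. SLC7A11 was higher in TET1-FL than in TET1-ALT (log2 1.87 ± 0.08, adjusted p = 4.77e-07), as were CHAC1 (1.83 ± 0.11, adjusted p = 4.64e-06), PCK2 (1.18 ± 0.08, adjusted p = 2.14e-05) and ASNS (1.15 ± 0.07, adjusted p = 4.64e-06). FUT1 (2.02), the collagen receptor gene DDR2 (1.20), JDP2 (2.14-fold), SLC6A9 (log2 1.09), ADM2 (1.27), CERKL (1.24), LPPR4 (1.17) and the lipoprotein lipase gene LPL (1.13) were higher too, with adjusted p-values from 7.38e-05 to 0.0251. HSPA1B (-1.54, adjusted p = 1.36e-06), HSPA8 (-0.97, adjusted p = 0.000498), DNAJB1 (-0.68, adjusted p = 0.00183) and DNAJA1 (-0.63, adjusted p = 0.0197) were lower in TET1-FL, as were CD3EAP (-0.75), HSPA2 (-0.64) and RHOV (-0.63), with adjusted p-values of 0.0119 to 0.0497. SRGAP2B, NBL1, TEN1-CDK3, PLSCR3 and POC1B-GALNT4 were also called lower, but their values swung between near 0 and higher levels among libraries or have overlapping partners and are uncertain. POC1B-GALNT4 was listed at 0 in all 3 TET1-FL libraries.

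Of 232 genes that differed between the isoforms, 121 were higher and 111 lower in TET1-FL, and 151 of them had also passed against the empty vector, all in the same direction. Both comparisons share the TET1-FL libraries, so part of this overlap and of its common direction may come from them. With each library rescaled to the same total, 190 were higher and 93 lower. The count was 943 without empty vector replicate 1 and 96 without empty vector replicate 2. It was 50, 42 and 50 without TET1-ALT replicates 1, 2 and 3, and 48, 143 and 41 without TET1-FL replicates 1, 2 and 3. It was 594 with only the 6 libraries of both groups.

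Between the isoforms the ATF4 list was higher in TET1-FL (15 of 29 rose, 14 did not pass, and 23 rose adjusted over the list alone; median 0.40, camera adjusted p = 4.20e-30, and adjusted p = 0.00167 with an estimated correlation). Camera called 6 other lists, and all 6 calls were lost with an estimated correlation. For the heat shock proteins (4 of 22 fell, 9 adjusted over the list alone, median -0.17) the adjusted p was 1.02e-06, and adjusted p = 0.479 with an estimated correlation. For cholesterol biosynthesis (2 of 24 fell, 5 adjusted over the list alone, median -0.13) it was 0.000388, and adjusted p = 0.479 with an estimated correlation. NSDHL was among the genes that fell (-0.37, adjusted p = 0.0468). For the immediate early genes (1 of 26 fell, 3 adjusted over the list alone, median -0.25) it was 0.00281, and adjusted p = 0.479 with an estimated correlation. JUN fell (-0.38, adjusted p = 0.0411), and JUNB was at -0.47. For the extracellular matrix list (1 of 27 rose, 2 adjusted over the list alone, median 0.11) it was 0.0113, and adjusted p = 0.535 with an estimated correlation. COL3A1 was the gene that rose (0.81, adjusted p = 0.0140), and the list call ended without TET1-FL replicate 2 (adjusted p = 0.148). In the developmental transcription factor list (59 measured, median -0.12) and the interferon-stimulated list (28 measured, median 0.07) no member passed over all genes or adjusted over the list alone, with adjusted p-values of 0.0224 and 0.0225, and adjusted p-values of 0.584 and 0.434 with an estimated correlation. The former call ended without TET1-ALT replicate 1 (median -0.06, adjusted p = 0.121) and TET1-FL replicate 3 (adjusted p = 0.0864). The latter ended without TET1-ALT replicate 2 (adjusted p = 0.0741) and TET1-FL replicate 2 (adjusted p = 0.0947), and its median was 0.11 and 0.12 without TET1-FL replicates 1 and 3. TBX2 was at -0.44 and ISL1 at -0.36 among the former, and IFIH1 at 0.59 and IFI44L at 0.48 among the latter. TET2 (-0.07), TET3 (-0.16), DNMT1 (-0.03), DNMT3A (-0.02), DNMT3B (0.01) and UHRF1 (-0.18) did not pass, with adjusted p-values from 0.360 to 0.967.

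**Figure D3:**
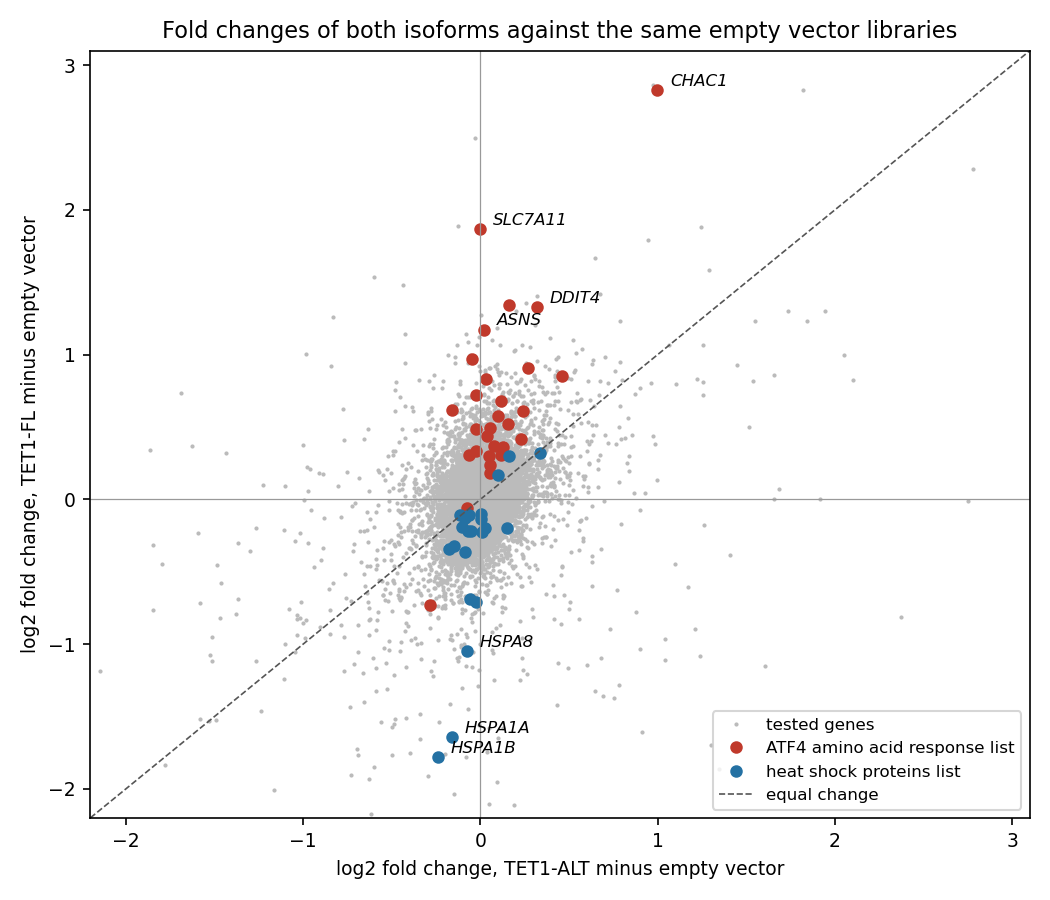
Log2 fold change against the empty vector in TET1-ALT (x axis) and TET1-FL (y axis) for each tested gene (gray), the ATF4 list (red) and the heat shock list (blue), with the line of equal change dashed. Of the tested genes, 33 lie outside the axes, TET1 and SLCO5A1 included. SLC7A11 and ASNS lie near 0 on the x axis and at 1.87 and 1.17 on the y axis, and HSPA1B lies at -0.24 and -1.78.

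Across genes, the log2 fold changes of both isoforms against the empty vector had a Pearson correlation of 0.39 (genes are not independent replicates) and a covariance of 0.0312. Groups simulated without any effect against the same 3 controls gave a mean correlation of 0.50 and a mean covariance of 0.0237 in 200 simulations. The correlation was below that simulated mean. Effects in TET1-FL alone would also lower it, and the simulated groups had none, so this comparison cannot tell whether effects were shared. Without TET1 and SLCO5A1, a choice made after the values were seen, the covariance was 0.0241 against 0.0237 simulated on average, a difference of 0.000317, and the correlation was 0.33. The highest simulated covariance without both was 0.0317. The 3 genes called higher in TET1-ALT, TET1, SLCO5A1 and CHAC1, were all called higher in TET1-FL, and of the genes called lower 0 were shared. Unchanged groups simulated against the same controls shared 0 genes called higher and 0.04 called lower on average in 50 simulations. Groups without any effect have few calls to share, so these counts are no baseline for the 3 shared calls. Independent lists would share 0.0289 and 0.0101, values that leave out the shared controls. TET1 was transfected in both groups and SLCO5A1 was at 0 in the shared controls, which leaves CHAC1 as the 1 shared gene not open to either. Of the other 272 genes called in TET1-FL, 71.3% had the same sign in TET1-ALT. Simulations that kept the TET1-FL effects and gave TET1-ALT none had 59.2% on average and at most 65.5% in 50 simulations. They were built from a residual spread for each gene, whereas genes of some lists varied together in the real libraries. The simulated range may therefore be too narrow to judge the 71.3%. The 3 controls could not be split, so part of the shared direction may come from them. A test over all 3 groups found 191 genes.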

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

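The alternatives voom, pseudocount 10, a mean of at least 50, removal of the length and GC trend, the joint omission of empty vector replicate 1 and TET1-FL replicate 1, and shared effects without TET1 and SLCO5A1 were chosen after seeing the data. TET1 kept its direction and calls in both overexpressing groups under all 25 alternatives, and did not pass between the isoforms under any of them. The counts of genes in TET1-FL against the empty vector (274), between the isoforms (232) and among the 3 groups (191) moved by over 1.5 times under several. With only the groups compared they were 54 and 594. Without a variance trend the isoform count was 104 and the 3-group count 79. With array weights, whose estimation stopped before convergence, these were 2228 and 1278, and with voom the isoform count was 149. With the length and GC trend removed the 3 counts were 1201, 876 and 866, and 270 of the 274 genes were among the 1201. Without empty vector replicate 1 and TET1-FL replicate 1 together they were 618, 620 and 428. The cause was not tested for any of these, although fewer samples entered the fits that left some out. Leaving out each library in turn gave 57 to 776, 41 to 943 and 42 to 854 genes, highest without empty vector replicate 1, which also stood apart on the first principal component. In TET1-ALT the count stayed at 3 to 5 under every alternative.

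The replicate numbers did not pair the samples: 2 of 9 same-numbered pairs correlated above 0.1 (range -0.24 to 0.25), and 3 of 9 samples correlated best with their own number. With the replicate block the counts were 119, 114 and 88 genes, and 4 in TET1-ALT.

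With an estimated correlation the called lists fell from 11 to 1 in TET1-FL, from 8 to 0 in TET1-ALT and from 7 to 1 between the isoforms, the ATF4 list being the 1 in both. Leaving out each library gave 5 to 9 lists in TET1-ALT. The ribosomal protein and respiratory chain medians in TET1-ALT reversed to -0.0157 and -0.0164 without TET1-ALT replicate 3, and their highest values over the libraries left out were 0.148 and 0.144. The developmental transcription factor median in TET1-ALT turned to -0.00921 without empty vector replicate 1, also with TET1-FL replicate 1 left out, and its highest value over the libraries left out was 0.113. Quantile normalization ended the calls of the interferon-stimulated, G1/S and TET1 partner lists in TET1-FL, at medians of 0.033, -0.0098 and -0.0478, and of the interferon-stimulated list between the isoforms (0.0439). Removal of the length and GC trend ended the call of the zinc finger list in TET1-FL (-0.0682). In TET1-ALT it ended those of the zinc finger (-0.0097), developmental transcription factor (0.0351) and immediate early (0.0242) lists. Between the isoforms it ended the developmental transcription factor call (-0.104). Array weights ended those of the G1/S list in TET1-FL (-0.0097) and of the developmental transcription factor (0.0408) and immediate early (0.0423) lists in TET1-ALT. Without a variance trend the TET1 partner call ended in TET1-FL (adjusted p = 0.0537), and with a mean of at least 50 the germline call in TET1-ALT (adjusted p = 0.219) and the interferon-stimulated call between the isoforms (adjusted p = 0.0560). Without empty vector replicate 1 and TET1-FL replicate 1 together the G1/S (-0.0102) and TGF-beta and BMP (0.101) calls ended in TET1-FL, and the germline (-0.136), developmental transcription factor and immediate early (0.0553) calls in TET1-ALT. Other medians moved by over 1.5 times with the call kept. In TET1-FL these were the TET1 partner (-0.0602), G1/S (-0.0146), ribosomal (0.103) and zinc finger (-0.0536) lists with equal totals, the interferon-stimulated (0.160), cholesterol (-0.0751) and ribosomal (0.126) lists with array weights, and the interferon-stimulated list with voom (0.168). In TET1-ALT they were the ATF4 (0.0788) and germline (-0.190) lists with array weights, and the ribosomal (0.0364), respiratory chain (0.0382) and germline (-0.0657) lists with the length and GC trend removed. The correlation of both isoforms' effects ranged from 0.298 to 0.523 over the libraries left out. Besides TET1, 13 of 32 named genes called in TET1-FL passed under every alternative, among them CHAC1, SLC7A11, ASNS, PCK2, HSPA1B and HSPA8. So did 12 of 28 between the isoforms and, in TET1-ALT, 1 of 3, the uncertain SLCO5A1. Other calls in TET1-FL were often lost. CLUL1 and HSPA1A passed under 13 of 24 alternatives. NSDHL, FEN1 and COL6A2 passed under 13 of 25, and CDC6, HIST1H2BF and UTP3 under 14 of 25. Between the isoforms HSPA2 passed under 11 of 25. Depth limits the weak genes: 3 fragments in TET1-FL replicate 1 are a value of 8.22.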

Other observations

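The lists of aminoacyl-tRNA synthetases and amino acid transporters, the test of the unfolded protein response list, and the genes named in this paragraph were chosen after the values were seen. Amino acid transporter genes outside the fixed ATF4 list rose in TET1-FL: SLC6A9 (log2 1.18, adjusted p = 0.000326), the neutral amino acid transporter genes SLC1A4 (0.89, adjusted p = 0.000229) and SLC38A2 (0.51, adjusted p = 0.00282), SLC43A1 (0.80, adjusted p = 0.00120) and SLC38A1 (0.32, adjusted p = 0.0459), by limma. These were 5 of 15 measured, and the other 10 did not pass. In TET1-ALT none of the 15 passed, at log2 fold changes of 0.10 for SLC6A9 and 0.03 for SLC1A4. Single members of lists that were not called also changed in TET1-FL. The cell cycle gene CCND1 fell (-0.48, adjusted p = 0.00991), as did WT1 (-0.53, adjusted p = 0.0276) and ADM (-0.43, adjusted p = 0.0282). VEGFA (0.41, adjusted p = 0.0144), the imprinted gene GRB10 (0.46, adjusted p = 0.00458) and the BH3-only gene BMF (0.47, adjusted p = 0.0270) rose. Of the 25 alternatives, ADM and SLC38A1 passed under 15, WT1 and BMF under 17, VEGFA under 20 and CCND1 under 23.

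The higher ATF4 list in TET1-FL was tested against technical explanations. The lowest list median over 3 scalings was 0.524, and with the length and GC trend removed it was 0.502, against 0.520. This argues against scaling and those trends as the whole cause. Thinning all libraries to 6.84 M fragments lowered the count of genes in TET1-FL against the empty vector from 274 to 131. The list median was then 0.501, so the rise was still there with equal numbers of fragments. Random thinning leaves the expected fold change of a well-counted gene as it was. This median could therefore hardly have fallen, and it does not test other differences that go with depth. TET1-ALT replicate 3, about as shallow as TET1-FL replicate 3, had a list median of 0.0970 against at least 0.481 in each TET1-FL library. That gap had been set beforehand as evidence against depth, but the criterion was wrong to rest on a single library, so depth stays open. As a hypothesis, full-length TET1 may activate an ATF4 programme. The transporters (median 0.106, and 7 rose and 1 fell adjusted over the list alone) and the aminoacyl-tRNA synthetases (0.138, 5 and 1) were called higher by limma camera at the preset correlation (adjusted p = 0.000121 and 0.0113). They were not called by camera with an estimated correlation (p = 0.0739 and 0.362, adjusted p = 0.148 and 0.362, not exact tests). Both lists were chosen after the values were seen, so their calls are no independent support, and a wider programme stays open. Some single genes were also looked at after the values were seen. By limma in TET1-FL, the ATF4 transcript itself (0.36, adjusted p = 0.0502), TRIB3 (0.24, adjusted p = 0.212) and ATF5 (-0.73, adjusted p = 0.117) did not pass. CTH (0.97, adjusted p = 4.61e-05) and PSAT1 (0.83, adjusted p = 4.61e-05) rose. Endoplasmic reticulum stress as the trigger also stays open: the unfolded protein response list had a median of -0.0714 (camera adjusted p = 0.266) over members that went both ways, 8 of 23 being above 0, and adjusted over the list alone 1 rose and 2 fell, with HERPUD1 at 0.42 (adjusted p = 0.0121), MANF at -0.42 (adjusted p = 0.0541) and HSPA5 at -0.71 (adjusted p = 0.0518), a value that was -0.46 (adjusted p = 0.0120) without empty vector replicate 1, where HSPA5 stood at 10144 against 5836 and 6086 in replicates 2 and 3, and the design does not separate an effect of TET1 on DNA from the load of a large expressed protein.

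The lower heat shock list in TET1-FL was weighed in the same way. HSPA1A and HSPA1B were both listed lower, which argues against reads moving between these paralogs. Their sum, nearly all of it HSPA1B, therefore had to fall too, and adds nothing further. It fell by 1.78 on the log2 scale (-1.777, upper limit of the 95% interval -1.59). The list median was -0.207 with the length and GC trend removed, against -0.208, which argues against those trends as the whole cause. With all libraries thinned it was -0.209, which does not decide on depth, for the reason given above. TET1-ALT replicate 3 was at -0.0491 against at most -0.189 in the TET1-FL libraries, again a single library, so that bound set beforehand adds nothing. The list call is lost with an estimated correlation (adjusted p = 0.433), so whether the list moved as a whole stays open, and no biological cause was tested.

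SLCO5A1 was listed at 0 in all 3 empty vector libraries and at 238 to 285 in the other 6. Too few fragments cannot account for it, since at least 253 would be drawn in each empty vector library at the lowest level of the other 6. A failed estimate for the whole group may account for it: 0 other genes were at 0 in a whole group and at 100 or more in the other 6 libraries, which had been set beforehand as evidence against it, but the lack of a second case excludes nothing. The reads would be needed to tell this from silence in the empty vector cells, and other causes were not tested.

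Other splits of the samples were counted. With only the 6 libraries compared in the fit, TET1-FL against the empty vector gave 54 genes and the highest of the other 9 splits gave 2. TET1-ALT gave 3 against a highest of 1, and the isoforms gave 594 against a highest of 1. These 10 splits per comparison are too few for a share under 0.05. For the 3 groups, 4 of 100 drawn splits, the real one included, gave at least the real 191 genes. That share is under 0.05, the bound set beforehand as evidence against chance. The others among these 4 divided the empty vector and TET1-ALT libraries in other ways and gave more genes, with 212, 326 and, as the highest, 479. The count therefore does not speak for the division between empty vector and TET1-ALT. All 6 drawn splits that kept the 3 TET1-FL libraries together gave 139 to 479 genes and no other split more than 4, so the larger counts follow TET1-FL against the rest, however the other 6 libraries were divided. No pair of replicates was close enough to be 1 library under 2 names, with a lowest chi-square per degree of freedom of 5.24.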
